A study of Arabidopsis thaliana with 12 samples.

How the data were processed

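The material was *Arabidopsis thaliana* ecotype Col-0, wild type. Per the labels' protocols, whole shoots of 14-day-old seedlings were pooled, about 300 plants per replicate, after growth on medium with 0.3 µM boric acid (the group Bminus, called low boron here), 30 µM (Ctrl) or 500 µM (Bplus, called high boron here). Each boron supply was measured by ribosome profiling and by RNA-seq, with 2 biological replicates per group and assay, 12 libraries in all. In ribosome profiling the stretch of mRNA that a ribosome covers is protected from a nuclease, and the protected pieces, the footprints, are sequenced. Per the labels' protocols, extracts held cycloheximide, which stops elongating ribosomes, footprints were cut with RNase I, and ribosomal RNA was depleted from the footprint samples with a Ribo-Zero kit. How the RNA-seq libraries were made was not given in the sources used here.

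The deposited tables hold raw counts, 1 table per assay, with 1 row for 1 transcript of each of 27655 genes. Per the file names, the footprint counts are P-sites (the codon position in the ribosome that holds the growing chain) summed over the coding sequence, and the RNA counts are reads over the same coding sequences. The authors named Bowtie2 and SAMtools, per the submitters' processing notes, and their versions, the genome build, the annotation, the read filters and the use of strand were not given in the sources used here. No coordinates are therefore printed. Gene names came from a RefSeq gene table of assembly TAIR10.1, in which 27445 of the 27655 gene IDs had a row and the other 210 (88 chloroplast-encoded and 122 mitochondria-encoded) did not. Counting within coding sequences leaves out footprints in 5′ leaders, and how reads shared by near-identical genes were assigned is not known, so values of such families (RBCS, LHCB1 and LHCB2, BIP1 and BIP2, GSTF6 and GSTF7, AOC, COR15, KIN, VSP, SAUR, XTH18 and XTH19) are uncertain for the single member.

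The columns name the group and carry replicate numbers 2 and 3, whereas the labels start from 1. Columns were therefore assigned to groups by name only, and a library is called here by its number in the table. Whether equal numbers mark a shared growth batch was tested through the correlation of the deviations of equal-numbered libraries. The numbers were not treated as pairs, and the fit with them as a block is among the alternatives.

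All tests were run on the counts as deposited, in R 4.3.3. mRNA and footprint changes were tested with the quasi-likelihood test of edgeR 4.0.16, with trimmed-mean (TMM) scaling, the default filter on low counts (filterByExpr), 1 coefficient per group, all 3 groups of the assay in 1 fit, and Benjamini-Hochberg adjustment with a threshold of 0.05. That left 18403 genes for mRNA and 17697 for footprints. Translation efficiency, the footprint level relative to the mRNA level of a gene, was tested as the interaction of assay and boron supply in 1 edgeR fit over all 12 libraries, scaled within each assay, for the 17306 genes that passed the filter in both. A called change is one with an adjusted p under 0.05. Values are log2 fold changes ± SE with 2 libraries per group, the SE being the absolute log2 fold change divided by the square root of the F statistic, and levels are CPM (edgeR's cpm, counts scaled to a common library size after TMM), as mean ± SD of the 2 libraries. The common biological coefficient of variation was 6.92% for mRNA, 14.9% for footprints and 11.1% in the joint fit.

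Before the data were examined, 28 gene lists, the tests and the rule for naming genes were fixed. For mRNA and for footprints, the rule took the 6 largest rises and the 6 largest falls per comparison with Ctrl among called genes with a mean log2 CPM of 1 or more and both treated libraries outside the range of the Ctrl libraries. For translation efficiency it took 4 and 4 with a mean log2 CPM of 1 or more in both assays, and for high against low boron 3 and 3, both without the condition on single libraries. It then took every member of the boron transport list and of the list of genes known before to carry an AUG-stop (an AUG directly followed by a stop codon) in the 5′ leader, and up to 3 called members of every other list. Lists were tested with camera in limma 3.58.1, which ranks the members against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, then with the correlation estimated, and with fry. Where a value is called adjusted within the list, the adjustment covered only that list's members. Where no such count is given, it equals the count given. No genome or transcript sequence was used here, so the planned lists of genes with an AUG-stop or another upstream AUG in the leader were not analysed here.

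Alternatives were DESeq2 size factors within edgeR, DESeq2 1.42.0, limma voom, no filter and a strict filter on low counts (a mean of 50 counts in every group), removal of organelle-encoded genes, a fit of only the groups compared (the 2-group fit), TMM over all libraries together, a 2-fold minimum, the replicate number as a block, the plant pool as a block shared by the assays, camera with the replicate block, and leaving out each library in turn. A fit with 1 library left in a group assumes that this library varies like those of the other groups. Alternatives added after seeing the data were the removal of a trend with genomic span from each library and the test of gene families by symbol.

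Tests were run on counts simulated with these libraries' means, depths and dispersions, 65 to 67 genes changing per fold. At low boron, 56.7% of the mRNA changes of 1.5-fold, 89.6% of 2-fold and 97% of 4-fold were recovered over 18017 genes fitted. For footprints these shares were 17.9%, 61.2% and 100% over 17324 genes, and for translation efficiency 4.48%, 37.3% and 98.5% over 16881 genes. For high boron they were 65.7%, 80.6% and 98.5% for mRNA, 13.4%, 62.7% and 97% for footprints, and 3.03%, 31.3% and 86.4% for translation efficiency, over 18020, 17338 and 16874 genes. Of simulated mRNA calls, 22 of 203 at low and 24 of 206 at high boron were unchanged genes. For footprints these were 12 of 143 and 11 of 140, and for translation efficiency 4 of 106 and 3 of 87. Only the mRNA and footprint shares exceed 0.05. Far more mRNAs were called in the data, where the shares need not hold. Of 50 unchanged simulated lists, at most 1 had a camera p under 0.05 in any comparison. This did not test the preset correlation on co-regulated lists. Figures were drawn with matplotlib.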

Results

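Ribosome footprints and mRNA of 27655 genes were counted in whole shoots of Col-0 seedlings grown with 0.3, 30 or 500 µM boric acid. Each of the 3 groups held 2 libraries per assay. The comparisons asked which genes differed from the 30 µM group (Ctrl) in mRNA, in footprints and in footprints per mRNA. Total RNA counts of libraries 2 and 3 were 9091475 and 8781846 for Ctrl, 8908016 and 8450732 for low boron, and 7563365 and 9256564 for high boron. Total footprint counts were 12274466 and 6903881 for Ctrl, 24206655 and 10015991 for low boron, and 13351151 and 7446195 for high boron. Between 19748 and 21160 genes had a count in a library, and the log CPM of replicate libraries correlated across genes at r = 0.9776 to 0.9905, genes not being independent replicates.

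NIP5;1 (AT4G10380), a boric acid channel of the plasma membrane, had the clearest boron response of the transport genes. Its mRNA rose at low boron from 11.1 ± 0.641 CPM (mean ± SD, n = 2) to 87.2 ± 5.75 CPM, a log2 change of 2.98 ± 0.11 (edgeR adjusted p = 4.09e-10). At high boron it fell to 5.19 ± 0.291 CPM (-1.1 ± 0.17, adjusted p = 0.000756). NIP5;1 footprints rose from 4.81 ± 0.368 to 97.4 ± 19.2 CPM at low boron (4.32 ± 0.22, adjusted p = 2.15e-08) and fell to 1.49 ± 0.019 CPM at high boron (-1.70 ± 0.30, adjusted p = 0.00728). That fall in footprints was lost without Ctrl library 2 (adjusted p = 0.0981) or high-boron library 2 (0.0885), and with limma voom (0.0588). The change in NIP5;1 translation efficiency missed the threshold at low boron (1.35 ± 0.25, adjusted p = 0.117) and at high boron (-0.60 ± 0.35, adjusted p = 0.707). At low boron it passed with DESeq2 (0.0261) and without low-boron footprint library 2 (0.0364), within a range of 0.0261 to 0.725 over the alternatives.

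BOR1 (AT2G47160), a boron exporter, changed in footprints but was not called in mRNA. Its mRNA differed from Ctrl by 0.04 ± 0.10 at low boron (adjusted p = 0.782) and -0.18 ± 0.10 at high boron (adjusted p = 0.305). BOR1 footprints fell at high boron from 12.6 ± 0.619 to 2.99 ± 0.164 CPM (-2.06 ± 0.24, adjusted p = 0.000431) and stood at 16.7 ± 0.421 CPM at low boron (0.41 ± 0.20, adjusted p = 0.205). Its translation efficiency fell at high boron by 1.87 ± 0.23 (adjusted p = 0.000622), a call kept in each alternative run, and was 0.37 ± 0.19 at low boron (adjusted p = 0.826). For AT3G62270, listed as the BOR1-related gene BOR2, mRNA rose at high boron (0.70 ± 0.20, adjusted p = 0.0428) while footprints (-1.50 ± 0.35, adjusted p = 0.0376) and translation efficiency (-2.18 ± 0.41, adjusted p = 0.0163) fell. The mRNA call was lost without Ctrl library 2 (adjusted p = 0.143), low-boron library 2 (0.0626) or 3 (0.0593), or high-boron library 2 (0.0575) or 3 (0.265), with DESeq2 (0.19) and in the 2-group fit (0.0574). The footprint call was lost without Ctrl library 2 (0.249) or 3 (0.0784), or high-boron library 2 (0.0528) or 3 (0.165), with voom (0.0858) and in the 2-group fit (0.0586). The efficiency call was lost without footprint libraries 2 of Ctrl (0.0896) or 3 of high boron (0.0534), or RNA libraries 2 of Ctrl (0.0617) or 3 of high boron (0.0967). At low boron AT3G62270 stood at 0.33 ± 0.21 in mRNA (adjusted p = 0.256), 0.80 ± 0.29 in footprints (0.0744) and 0.47 ± 0.36 in efficiency (0.859), the footprint change passing with no filter (0.0262) and without high-boron library 2 (0.0475).

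Among the other transport genes, mRNA of NIP6;1 (AT1G80760), a boric acid channel, rose at high boron (0.63 ± 0.17, adjusted p = 0.0285). That call was lost without Ctrl library 2 (0.0767), or high-boron library 2 (0.0761) or 3 (0.15), and with DESeq2 (0.15). NIP6;1 was not called in mRNA at low boron (0.37 ± 0.17) or in footprints (0.27 ± 0.21 and 0.62 ± 0.21). The mRNA of AT3G06450, listed as BOR3, rose at low boron (0.33 ± 0.08, adjusted p = 0.00753), a call lost without low-boron library 2 (0.101) and with DESeq2 (0.0532). AT3G06450 was not called in mRNA at high boron (-0.02 ± 0.09) or in footprints (0.42 ± 0.18 at low boron, 0.03 ± 0.19 at high boron). BOR5 (AT1G74810) was not called in any comparison with Ctrl (mRNA -0.37 ± 0.28 and 0.40 ± 0.26, footprints 0.02 ± 0.53 and 0.78 ± 0.53 at low and high boron). Its mRNA passed at low boron without Ctrl library 3 (-0.73, 0.0288) and at high boron without Ctrl library 2 (0.90, 0.0347). The translation efficiency of NIP6;1, AT3G06450 and BOR5 was not called either, and the other 5 listed transport genes, among them BOR4 and NIP7;1, had 0 to 5 counts per library and were not tested. As a list, 2 of 6 tested genes rose and 0 fell in mRNA at low boron, 2 of 6 adjusted within the list (camera adjusted p = 0.00887; adjusted p = 0.454 with correlation estimated). At high boron 2 rose and 1 fell in mRNA (camera adjusted p = 0.824). In footprints 1 rose at low boron, 2 adjusted within the list (9.71e-05; adjusted p = 0.33 with correlation estimated). Footprints of 3 fell at high boron, 1 rising and 3 falling adjusted within the list (0.00131; adjusted p = 0.307 with correlation estimated). In efficiency, 2 fell at high boron and 2 adjusted within the list (0.000139; adjusted p = 0.246 with correlation estimated). At low boron 0 were called in efficiency with edgeR and voom, 1 with DESeq2 and 1 at unadjusted p < 0.05, and 1 rose adjusted within the list (0.00223; adjusted p = 0.422 with correlation estimated).

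**Figure D1:**
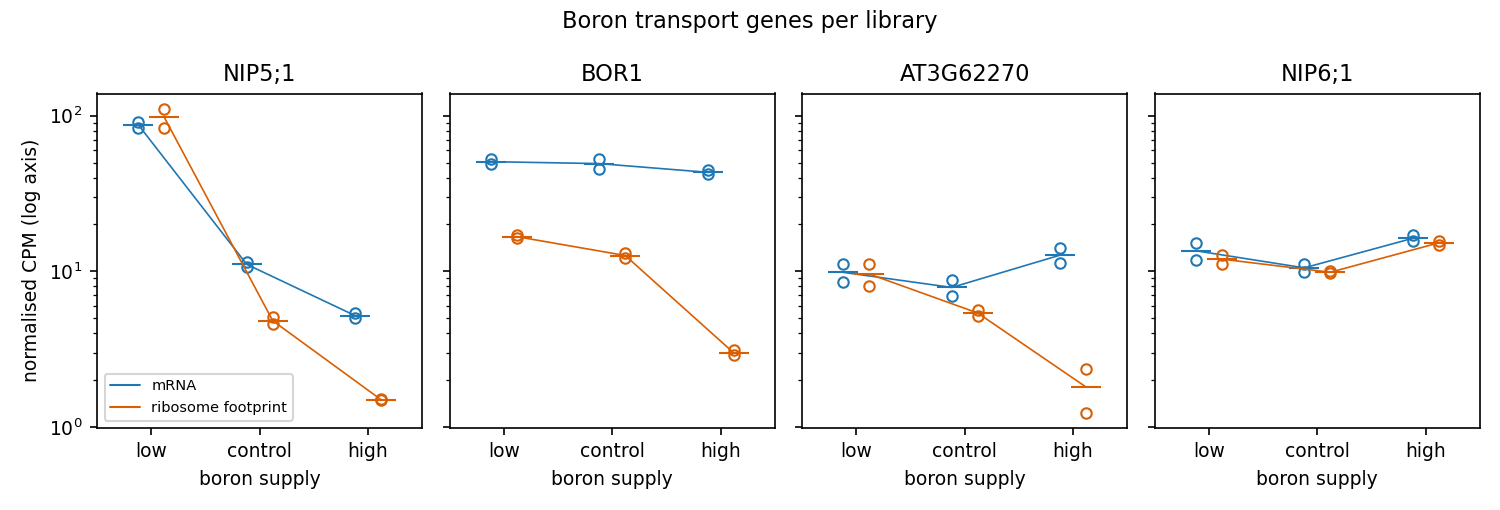
Normalised CPM (log axis) of NIP5;1, BOR1, AT3G62270 and NIP6;1 at low, control and high boron, mRNA in blue and footprints in orange, with 1 open circle per library and a dash at the mean of 2. NIP5;1 moved in both assays, from 4.81 CPM in control footprints to 97.4 CPM at low boron, and BOR1 footprints fell to 2.99 CPM at high boron.

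The list of genes known before to carry an AUG-stop in the 5′ leader held NIP5;1, ABS2 (AT2G36080) and SKU5 (AT4G12420). ABS2, a transcription factor also named NGAL1, rose at low boron in mRNA (1.60 ± 0.13, adjusted p = 5.01e-07) and in footprints (1.3 ± 0.23, adjusted p = 0.0013) and was not called at high boron (-0.09 ± 0.15 and 0.19 ± 0.24). SKU5, a protein of directional root growth, was not called at low boron (0.07 ± 0.08 and 0.18 ± 0.17), and at high boron fell in mRNA (-0.39 ± 0.08, adjusted p = 0.00572) and in footprints (-0.82 ± 0.17, adjusted p = 0.0228). The footprint fall of SKU5 was lost without Ctrl library 2 (0.0642) or 3 (0.0872), or high-boron library 2 (0.0845) or 3 (0.0935). In translation efficiency edgeR and voom called 0 of the 3, with 1 at unadjusted p < 0.05 at low and at high boron, and DESeq2 called 1, NIP5;1, at low boron and 0 at high boron. Of these 3 genes, 2 rose at low boron and 2 fell at high boron in each assay. The list was called at low boron in mRNA (camera adjusted p = 1.93e-07; adjusted p = 0.183 with correlation estimated) and footprints (7.35e-08; adjusted p = 0.222 with correlation estimated). At high boron it was called in mRNA (0.0153; adjusted p = 0.799 with correlation estimated) and footprints (0.00278; adjusted p = 0.307 with correlation estimated). In efficiency, 1 gene rose at low boron adjusted within the list (0.0245; adjusted p = 0.422 with correlation estimated), and the list was not called at high boron (0.354).

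At low boron, the defence, jasmonate and unfolded protein lists were called upward in mRNA and photosynthesis downward. Of 18 salicylic acid and defence genes 17 rose, among them FMO1 (AT1G19250, 3.13 ± 0.14), which makes the signal N-hydroxypipecolic acid, the defence regulator PAD4 (AT3G52430, 2.42 ± 0.12) and the salicylate exporter EDS5 (AT4G39030, 2.32 ± 0.12). Of 24 jasmonate genes 21 rose, including the repressor JAZ1 (AT1G19180, 2.08 ± 0.11) and the synthesis enzymes LOX2 (AT3G45140, 1.57 ± 0.10) and AOC3 (AT3G25780, 2.52 ± 0.17). All 11 tested genes of the unfolded protein response rose, with the chaperone BIP3 (AT1G09080) at 2.62 ± 0.17, ATERDJ3B (AT3G62600) at 1.1 ± 0.09 and BIP2 (AT5G42020) at 0.96 ± 0.08. Of 32 nuclear photosynthesis genes 27 fell and 0 rose, among them the Rubisco small subunits RBCS2B (AT5G38420, -1.15 ± 0.11), RBCS1B (AT5G38430, -0.90 ± 0.10) and RBCS3B (AT5G38410, -0.68 ± 0.09). These lists were called with camera (adjusted p = 9e-33, 7.58e-21, 3.84e-16 and 1.85e-11), with 17, 23 and 11 rising, and 2 rising and 28 falling, adjusted within the list. With an estimated correlation no list was called in either assay at either supply, here at adjusted p = 0.0686, 0.183, 0.183 and 0.28.

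The senescence, oxidative stress and glucosinolate lists were also called upward in mRNA at low boron. Of 11 senescence genes 9 rose and 1 fell (camera adjusted p = 5.33e-07; adjusted p = 0.189 with correlation estimated). WRKY53 (AT4G23810) stood at 1.81 ± 0.13, SEN1 (AT4G35770) at 2.4 ± 0.23 and SAG21 (AT4G02380) at 1.32 ± 0.08. Of 18 oxidative stress genes 11 rose and 3 fell, 12 and 3 adjusted within the list (9.62e-06; adjusted p = 0.189 with correlation estimated). GSTF6 (AT1G02930) stood at 1.91 ± 0.10, GSTF7 (AT1G02920) at 1.48 ± 0.08 and RHL41 (AT5G59820) at 2.11 ± 0.22. Of 20 glucosinolate genes 9 rose, 10 adjusted within the list, including the regulator MYB51 (AT1G18570, 1.16 ± 0.10), SOT16 (AT1G74100, 0.81 ± 0.09) and CYP83B1 (AT4G31500, 0.80 ± 0.09) (0.0127; adjusted p = 0.751 with correlation estimated). Pectin and RG-II synthesis, which makes the wall polymer that borate cross-links, had 8 of 14 genes higher and 0 lower, 9 adjusted within the list (0.0719). UGD3 (AT5G15490) stood at 0.51 ± 0.09, UGD2 (AT3G29360) at 0.42 ± 0.09 and TSD2 (AT1G78240) at 0.40 ± 0.09. Of 32 wall loosening genes 10 rose and 7 fell, 11 and 8 adjusted within the list (0.599). XTH18 (AT4G30280) stood at 2.93 ± 0.22, XTR6 (AT4G25810) at 1.61 ± 0.15 and TCH4 (AT5G57560) at 1.33 ± 0.13. This list had a median of -0.08, a mean of 0.16 and a test direction upward. Of 24 abscisic acid and cold genes 2 rose and 5 fell, with COR15B (AT2G42530) at -1.83 ± 0.17, ABI1 (AT4G26080) at 0.48 ± 0.10 and LTI78 (AT5G52310) at 0.38 ± 0.09. LTI78 was lost without low-boron library 2 (0.0692), and the list had a median of 0.06 and a mean of -0.12 with a downward test (0.445).

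Lists with few members called at low boron in mRNA were heat shock (1 of 7 rose, HSP90.1, AT5G52640, 1.21 ± 0.11; camera adjusted p = 0.383), anthocyanin (1 of 14 rose, LDOX, AT4G22880, 1.05 ± 0.20; 0.599) and phosphate starvation (3 of 9 fell; 0.111). The phosphate genes were SQD2 (AT5G01220, -0.53 ± 0.11), SQD1 (AT4G33030, -0.33 ± 0.08) and MGDC (AT2G11810, -0.94 ± 0.32). SQD1 was lost without low-boron library 3 (0.0742), and MGDC without Ctrl library 2 (0.1) or low-boron library 3 (0.3) and with DESeq2 (0.104). Of 17 cell cycle genes 3 fell: CYCD3;1 (AT4G34160, -0.50 ± 0.12), MCM2 (AT1G44900, -0.37 ± 0.10) and SYP111 (AT1G08560, -0.46 ± 0.13) (0.132). All 3 were lost without low-boron library 3 (0.0646, 0.144 and 0.0967), SYP111 also without Ctrl library 3 (0.222) or low-boron library 2 (0.0842), and MCM2 with DESeq2 (0.086). In sulfur deficiency 1 rose (AT5G26220, 0.94 ± 0.15) and 1 fell (AT1G04770, -0.45 ± 0.15) of 11 (0.742), and AT1G04770 was lost without Ctrl library 3 (0.158) or low-boron library 2 (0.247) and with DESeq2 (0.142). In DNA damage 1 of 10 fell and 0 adjusted within the list (TSO2, AT3G27060, -0.30 ± 0.09; 0.56), a call lost without Ctrl library 3 (0.102) or low-boron library 3 (0.32) and with DESeq2 (0.0736). Of 3 ferritin genes 1 fell (FER3, AT3G56090, -0.43 ± 0.13; 0.599), 1 rising and 2 falling adjusted within the list, and FER3 was lost without Ctrl library 2 (0.0889) or low-boron library 2 (0.0887) or 3 (0.141). Of 8 cellulose synthases (median 0.03, mean -0.06, downward; 0.712) and 9 iron deficiency genes (0.63), the 3 tools (edgeR, DESeq2 and voom) called 0, with 1 and 0 at unadjusted p < 0.05.

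Across all 18403 genes tested for mRNA at low boron, 6120 were called (33.3%), 3582 higher and 2538 lower, and 1250 changed at least 2-fold, 995 of them higher. The largest rise by fit was AT1G76470, with 97 counts against 1 in Ctrl, a ratio of 99.7 with a 95% counting interval of 17.5 to 3980 that covers counting error only. After it came AT3G60470 (4.82 ± 0.47), the tyrosine aminotransferase TAT3 (AT2G24850, 4.75 ± 0.26), the acetyltransferase NATA1 (AT2G39030, 4.66 ± 0.38), AIG1 (AT1G33960, 4.53 ± 0.14) and AT1G57650 (4.48 ± 0.50). The largest falls were those of JMJD5 (AT3G20810, -3.25 ± 0.16), SAUR68 (AT1G29510, -2.83 ± 0.65), AT3G55710 (-2.66 ± 0.36), the flowering regulator CO (AT5G15840, -2.45 ± 0.54, -3.68 without low-boron library 2), the germin-like protein GER3 (AT5G20630, -2.33 ± 0.09) and RVE2 (AT5G37260, -2.08 ± 0.19). JMJD5, CO and RVE2 are known to cycle over the day. SAUR68 was lost without low-boron library 2 (0.0595). The count was 4035 without low-boron library 2, 3731 without library 3 and 4030 with DESeq2.

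The same 4 lists and senescence were called in low-boron footprints, photosynthesis downward and the others upward. Of 18 salicylic acid and defence genes 16 rose, 18 adjusted within the list (camera adjusted p = 3.3e-23; adjusted p = 0.222 with correlation estimated). The glucanase BGL2 (AT3G57260, known as PR2) stood at 2.71 ± 0.26, PBS3 (AT5G13320) at 2.00 ± 0.21 and FMO1 at 1.98 ± 0.21. Of 25 jasmonate genes 16 rose, 18 adjusted within the list (6.75e-19; adjusted p = 0.222 with correlation estimated). The jasmonate-oxidising CYP94C1 (AT2G27690) stood at 2.67 ± 0.23, JAZ10 (AT5G13220) at 2.51 ± 0.27 and JAZ1 at 1.56 ± 0.17. Of 11 unfolded protein response genes 7 rose, 11 adjusted within the list (7e-07; adjusted p = 0.33 with correlation estimated). BIP3 stood at 2.13 ± 0.21. ATERDJ3B (0.76 ± 0.18) was lost without Ctrl library 2 (0.0786) or low-boron library 2 (0.1). CRT1b (AT1G09210, 0.74 ± 0.18) was lost without Ctrl library 2 (0.101) or low-boron library 3 (0.109). Of 32 photosynthesis genes 11 fell, 19 adjusted within the list (4.27e-09; adjusted p = 0.611 with correlation estimated). RBCS2B stood at -1.27 ± 0.20. RBCS1B (-1.09 ± 0.21) was lost without Ctrl library 2 (0.0504) or low-boron library 3 (0.0711). PSAE-1 (AT4G28750, -1.09 ± 0.21) was lost without low-boron library 3 (0.0645). Of 12 senescence genes 6 rose, 6 rising and 1 falling adjusted within the list (0.00037; adjusted p = 0.33 with correlation estimated). SEN1 stood at 1.74 ± 0.20, WRKY53 at 1.21 ± 0.21 and NAC6 (AT5G39610) at 0.95 ± 0.17.

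**Figure D2:**
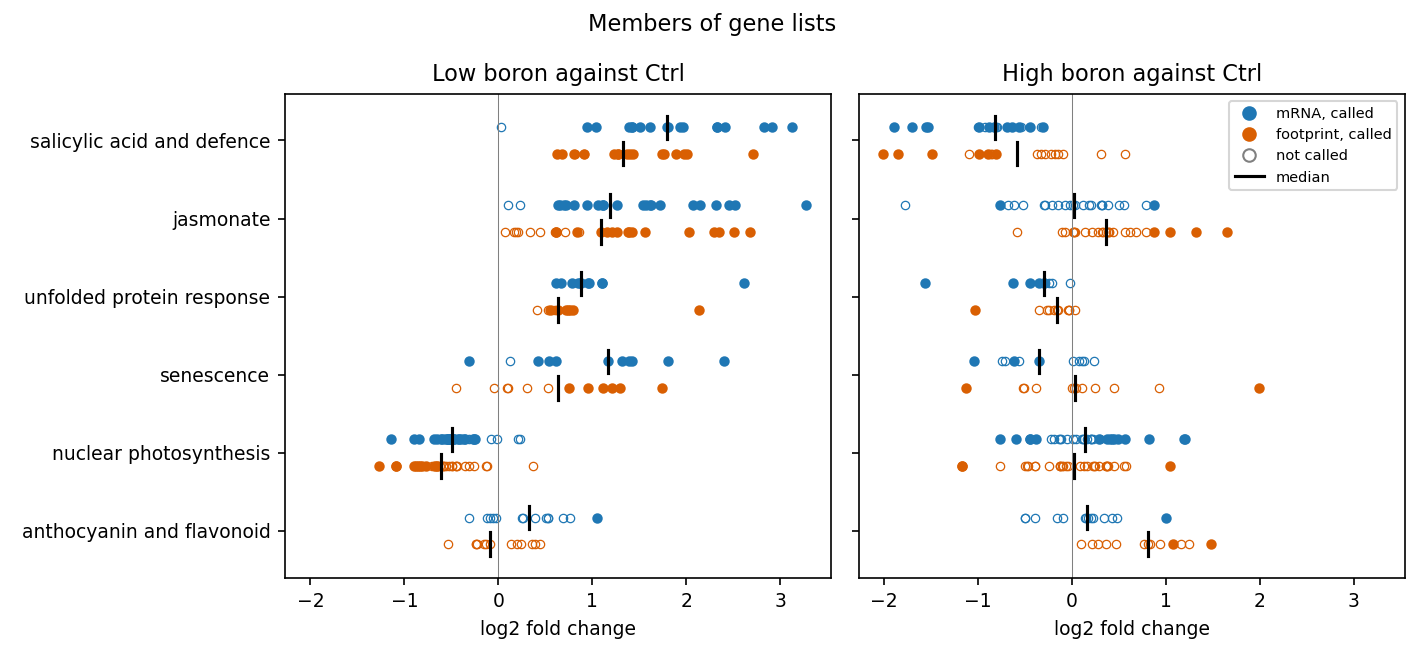
log2 fold changes against Ctrl (horizontal axis) of the members of 6 gene lists at low boron and at high boron, mRNA in blue and footprints in orange, with filled points for called genes, open points for the others and a black bar at the median. The salicylic acid and defence list lay at a median of 1.80 in mRNA at low boron and -0.82 at high boron, and the anthocyanin list at 0.81 in footprints at high boron.

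Further lists were called in low-boron footprints with camera. Of 18 oxidative stress genes 5 rose and 2 fell, 8 and 2 adjusted within the list (0.0484; adjusted p = 0.666 with correlation estimated). BAP1 (AT3G61190) stood at 1.56 ± 0.25, GSTF6 at 1.16 ± 0.20 and the superoxide dismutase FSD1 (AT4G25100) at -1.67 ± 0.28 (-1.0 without Ctrl library 2). Of 14 pectin genes 2 rose (0.0122; adjusted p = 0.611 with correlation estimated). TSD2 (0.76 ± 0.18) was lost without Ctrl library 2 (0.0978) or low-boron library 2 (0.0639) or 3 (0.065). GAE1 (AT4G30440, 0.72 ± 0.23) was lost without Ctrl library 2 (0.378) or low-boron library 3 (0.354) and in the 2-group fit (0.051). Of 17 cell cycle genes 4 fell, 7 adjusted within the list (0.00127; adjusted p = 0.611 with correlation estimated), among them SYP111 (-0.71 ± 0.19), CYCB1;4 (AT2G26760, -0.85 ± 0.25) and CYCA1;1 (AT1G44110, -0.57 ± 0.17). Without low-boron library 3 these 3 were lost (0.288, 0.307 and 0.319), and without Ctrl library 2 as well (0.102, 0.12 and 0.172). CYCB1;4 and CYCA1;1 were also lost without Ctrl library 3 (0.0777 and 0.058), and CYCA1;1 without low-boron library 2 (0.12). Of 9 phosphate genes 3 fell (0.0122; adjusted p = 0.666 with correlation estimated). MGDC stood at -1.49 ± 0.29. SQD2 (-0.72 ± 0.18) and SPX1 (AT5G20150, -0.72 ± 0.18) were lost without Ctrl library 3 (0.0859 and 0.0814) or low-boron library 2 (0.127 and 0.125) or 3 (0.0848 and 0.102).

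The other lists were not called in low-boron footprints. Of 31 wall loosening genes 7 rose and 3 fell, 8 and 5 adjusted within the list (median -0.23, mean 0.05, upward; 0.525). XTH18 stood at 2.38 ± 0.18, XTH19 (AT4G30290) at 2.00 ± 0.24 and the expansin EXPA8 (AT2G40610) at -1.74 ± 0.21. Of 23 abscisic acid and cold genes 2 rose and 3 fell (0.393). COR15B fell by 2.23 ± 0.20, while COR15A (AT2G42540, -1.16 ± 0.35) was lost without Ctrl library 2 (0.11) or 3 (0.0998), or low-boron library 2 (0.113) or 3 (0.156). KIN2 (AT5G15970, -0.80 ± 0.24) was lost without Ctrl library 2 (0.446) or low-boron library 2 (0.272). In sulfur deficiency 1 of 11 rose and 2 fell (0.331). ATSDI1 (AT5G48850, -1.28 ± 0.31) was lost without Ctrl library 2 (0.0538) or 3 (0.0537) or low-boron library 2 (0.18), AT5G26220 (0.80 ± 0.21) without Ctrl library 3 (0.089) or low-boron library 3 (0.178). APR3 (AT4G21990, -0.66 ± 0.18) was lost without Ctrl library 2 (0.0997) or low-boron library 3 (0.298). Single genes were called among 20 glucosinolate genes (MYB122, AT1G74080, 2.79 ± 0.63; list 0.331), 6 heat shock genes (AT5G37670, -1.41 ± 0.39; 0.509), 10 DNA damage genes (GMI1, AT5G24280, 0.71 ± 0.22; median -0.27; 0.492) and 8 iron deficiency genes (NAS4, AT1G56430, -0.90 ± 0.22; 0.504). Adjusted within the list these counts were 1, 1, 0 and 1. Without Ctrl library 2 these 4 calls were lost (0.0556, 0.338, 0.264 and 0.0844), and without low-boron library 2 the last 3 (0.12, 0.172 and 0.183). Without low-boron library 3 the first 3 were lost (0.0621, 0.119 and 0.177), and without Ctrl library 3 MYB122 (0.0531) and GMI1 (0.0523). DESeq2 did not call AT5G37670 (0.0524) or GMI1 (0.0712). Of 8 cellulose synthases (median 0.07, mean -0.12; 0.666), 13 anthocyanin genes (median -0.09, mean 0.01; 0.919) and 3 ferritin genes (0.612), the 3 tools called 0, with 4, 0 and 2 at unadjusted p < 0.05.

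Of the 17697 genes tested in footprints, 2650 were called at low boron (15%), 1425 higher and 1225 lower, and 1114 changed at least 2-fold, 724 of them higher. The largest rises were those of AT3G53400 (5.15 ± 0.24), the glutamine amidotransferase-like gene GAT1_2.1 (AT1G15040, 4.88 ± 0.29), AT2G38240 (4.75 ± 0.52), CPUORF47 (AT5G03190, 4.63 ± 0.25), NIP5;1 and AT3G28600 (4.21 ± 0.64, 8.94 without Ctrl library 2). The largest falls were those of AT3G53250 (-2.79 ± 0.43), GER3 (-2.62 ± 0.23), AT3G55710 (-2.58 ± 0.35), AT5G18030 (-2.56 ± 0.54), PnsL3 (AT3G01440, -2.24 ± 0.18), a subunit of the chloroplast NDH complex, and COR15B. The count was 1211 without Ctrl library 2, 1551 without low-boron library 2 and 922 without low-boron library 3.

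At high boron, the defence and unfolded protein lists were called downward in mRNA, and photosynthesis and abscisic acid upward. Of 18 salicylic acid and defence genes 12 fell and 0 rose in mRNA, 14 adjusted within the list (camera adjusted p = 3.02e-16; adjusted p = 0.128 with correlation estimated). Among them were WRKY70 (AT3G56400, -1.56 ± 0.15), the camalexin enzyme PAD3 (AT3G26830, -1.70 ± 0.20) and FMO1 (-1.89 ± 0.25). Of 11 unfolded protein response genes 5 fell, 10 adjusted within the list (1.74e-06; adjusted p = 0.799 with correlation estimated). BIP3 stood at -1.57 ± 0.28, BIP2 at -0.63 ± 0.08 and BIP1 (AT5G28540) at -0.45 ± 0.08. Of 32 photosynthesis genes 10 rose and 5 fell, 13 and 5 adjusted within the list (0.00253; adjusted p = 0.903 with correlation estimated). The rises included the light-harvesting proteins LHCB2.1 (AT2G05100, 1.19 ± 0.09), LHCB2.3 (AT3G27690, 1.21 ± 0.10) and LHCB2.2 (AT2G05070, 0.82 ± 0.09), and the 5 that fell were GAPA, RBCS2B, RBCS1B and the light-harvesting proteins LHCA2 and CAB1. Of 24 abscisic acid and cold genes 4 rose, 6 rising and 1 falling adjusted within the list (0.00871; adjusted p = 0.799 with correlation estimated). COR15A stood at 1.28 ± 0.22, LTI78 at 0.66 ± 0.09 and KIN2 at 0.54 ± 0.10. Of 24 jasmonate genes 1 rose, CORI3 (AT4G23600, 0.87 ± 0.13), and 1 fell, LOX4 (AT1G72520, -0.77 ± 0.21) (median 0.02, mean -0.04, upward; 0.765). LOX4 was lost without Ctrl library 2 (0.0762), low-boron library 2 (0.0559) or 3 (0.0512), or high-boron library 2 (0.0761) or 3 (0.187), with DESeq2 (0.128), with voom (0.0588) and in the 2-group fit (0.0805).

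In mRNA at high boron 3 of 11 senescence genes fell, 6 adjusted within the list (0.0153; adjusted p = 0.799 with correlation estimated). WRKY53 stood at -1.04 ± 0.16, SAG21 at -0.61 ± 0.09 and NYC1 (AT4G13250) at -0.35 ± 0.09. NYC1 was lost without Ctrl library 2 (0.17), low-boron library 2 (0.0738) or 3 (0.0732), or high-boron library 2 (0.216), and in the 2-group fit (0.0764). Of 20 glucosinolate genes 1 rose and 3 fell, 2 and 7 adjusted within the list (0.0371; adjusted p = 0.903 with correlation estimated). MYB51 stood at -0.66 ± 0.11, CYP83B1 at -0.53 ± 0.09 and IMS2 (AT5G23020) at -0.49 ± 0.10. IMS2 was lost without high-boron library 3 (0.0538). Of 18 oxidative stress genes 4 rose and 3 fell (median 0.02, downward test; 0.824). The catalase CAT2 (AT4G35090) stood at 1.06 ± 0.11, GSTF7 at -1.34 ± 0.09 and GSTF6 at -1.07 ± 0.11. Of 32 wall loosening genes 2 rose and 1 fell (0.26). XTH15 (AT4G14130) stood at 0.92 ± 0.12, XTH24 (AT4G30270) at 0.48 ± 0.09 and XTH25 (AT5G57550) at -1.0 ± 0.26. XTH25 was lost without Ctrl library 2 (0.0892) or high-boron library 2 (0.189), with DESeq2 (0.0781) and in the 2-group fit (0.0663). Of 14 pectin genes 1 rose and 2 fell (0.824). GAUT1 (AT3G61130, 0.36 ± 0.08) was lost without high-boron library 3 (0.0685). RGXT3 (AT1G56550, -1.54 ± 0.37) was lost without high-boron library 2 (0.118). RGXT2 (AT4G01750, -0.56 ± 0.16) was lost without Ctrl library 3 (0.193), low-boron library 2 (0.0821) or 3 (0.081) or high-boron library 2 (0.344), with DESeq2 (0.131) and in the 2-group fit (0.091).

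Single genes of 5 more lists rose or fell in mRNA at high boron, each losing its call without 1 or more libraries. They were F3H (AT3G51240, 1.00 ± 0.25) among 14 anthocyanin genes (0.756), and HSP18.2 (AT5G59720, 1.03 ± 0.22) among 7 heat shock genes (0.824). The others were SOG1 (AT1G25580, -0.56 ± 0.15) among 10 DNA damage genes (median 0.01, mean -0.02, downward; 0.824), MGDC (1.06 ± 0.25) among 9 phosphate genes (median -0.07, mean 0.04, upward; 0.824), and APR2 (AT1G62180, 0.46 ± 0.10) and AT1G04770 (-0.56 ± 0.15) among 11 sulfur deficiency genes (0.581). Adjusted within the list, 1 more heat shock gene fell and the other counts stayed. Without Ctrl library 2, F3H (0.0737) and SOG1 (0.124) were lost, and without Ctrl library 3 AT1G04770 (0.133). Without low-boron libraries 2 or 3, SOG1 (0.0567 and 0.0551) and AT1G04770 (0.0522 and 0.0512) were lost. Without high-boron library 2, F3H (0.161), HSP18.2 (0.0825), MGDC (0.0824), APR2 (0.0691) and AT1G04770 (0.0677) were lost, and without library 3 SOG1 (0.193), MGDC (0.0704) and AT1G04770 (0.208). DESeq2 did not call F3H (0.0958), SOG1 (0.13), MGDC (0.08) or AT1G04770 (0.155), and the 2-group fit did not call SOG1 (0.0649) or AT1G04770 (0.0561). Of 8 cellulose synthases (0.454), 17 cell cycle genes (0.824), 9 iron deficiency genes (0.824) and 3 ferritin genes (0.824), the 3 tools called 0, with 1, 1, 0 and 0 at unadjusted p < 0.05.

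Of the genes tested for mRNA, 1667 were called at high boron (9.06%), 829 higher and 838 lower, and 349 changed at least 2-fold, 237 of them lower. The largest rises were those of the beta-amylase BAM5 (AT4G15210, 3.15 ± 0.30), the cytochrome P450 CYP81D11 (AT3G28740, 2.95 ± 0.13), AT2G15020 (2.62 ± 0.38), the glucosyltransferases UGT74E2 (AT1G05680, 2.60 ± 0.46) and UGT73C1 (AT2G36750, 2.19 ± 0.35), and AT4G19430 (2.35 ± 0.12). AT5G52720 had 1 count against 18 in Ctrl, a ratio of 0.0578 (95% counting interval 0.00139 to 0.366), and was lost without high-boron library 2 (0.143) or 3 (0.0512). The other large falls were those of ARD3 (AT2G26400, -3.62 ± 0.28), an enzyme of methionine salvage, AT3G28510 (-3.14 ± 0.29), PCR1 (AT1G14880, -3.06 ± 0.21), AT1G72060 (-3.02 ± 0.55) and the receptor-like kinase CRK4 (AT3G45860, -2.94 ± 0.28). The count was 784 without high-boron library 2, with 441 higher and 343 lower, and 963 with DESeq2.

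At high boron, the defence list was called downward in footprints and the flavonoid and jasmonate lists upward. Of 18 salicylic acid and defence genes 6 fell and 0 rose, 9 adjusted within the list (camera adjusted p = 2.06e-10; adjusted p = 0.307 with correlation estimated). FMO1 stood at -1.49 ± 0.24. EDS1 (AT3G48090, -0.89 ± 0.17) was lost without Ctrl library 2 (0.13) or high-boron library 2 (0.0853) or 3 (0.0518). EDS16 (AT1G74710, -0.99 ± 0.20) was lost without Ctrl library 2 (0.0631) or 3 (0.0747) or high-boron library 2 (0.185). Of 13 anthocyanin and flavonoid genes 2 rose, 6 adjusted within the list (7.31e-10; adjusted p = 0.191 with correlation estimated). Chalcone synthase TT4 (AT5G13930) stood at 1.48 ± 0.19. The reductase DFR (AT5G42800, 1.08 ± 0.23) was lost without Ctrl library 2 (0.244) or 3 (0.0738) or high-boron library 2 (0.179). Of 25 jasmonate genes 4 rose, 6 adjusted within the list (3.51e-08; adjusted p = 0.333 with correlation estimated). The storage protein VSP1 (AT5G24780) stood at 1.65 ± 0.23. VSP2 (AT5G24770, 1.31 ± 0.23) was lost without Ctrl library 2 (0.105). TIFY7 (AT1G70700, 0.87 ± 0.17) was lost without Ctrl library 2 (0.112) or 3 (0.0636) or high-boron library 2 (0.0848). Of 23 abscisic acid and cold genes edgeR and voom called 0 and DESeq2 1, with 6 at unadjusted p < 0.05, and 2 rose adjusted within the list, while the list was called upward (0.000436; adjusted p = 0.3 with correlation estimated). Of 11 unfolded protein response genes 1 fell (0.0494; adjusted p = 0.749 with correlation estimated). It was BIP3 (-1.03 ± 0.23), lost without Ctrl library 2 (0.0549) or 3 (0.124) or high-boron library 2 (0.282) and in the 2-group fit (0.0563).

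Of 20 glucosinolate genes in high-boron footprints the 3 tools called 0, with 4 at unadjusted p < 0.05, and the list was called downward (0.0383; adjusted p = 0.833 with correlation estimated). Of 18 oxidative stress genes 1 rose, GSTU24 (AT1G17170, 1.74 ± 0.25), and 1 fell, GSTF7 (-0.98 ± 0.19), 2 and 2 adjusted within the list (0.64), GSTF7 being lost without Ctrl library 2 (0.108) or high-boron library 2 (0.113). Of 32 photosynthesis genes 1 rose and 2 fell, 1 and 3 adjusted within the list (median 0.02, mean -0.01, downward; 0.897). GAPA (AT3G26650), an enzyme of the Calvin cycle, fell by 1.17 ± 0.20. LHCB2.1 (1.04 ± 0.23) was lost without Ctrl library 2 (0.244) or 3 (0.136) or high-boron library 3 (0.28). CAB1 (AT1G29930, -1.17 ± 0.27) was lost without Ctrl library 2 (0.195) or 3 (0.0907) or high-boron library 2 (0.153) and under the strict filter (0.0515). Of 12 senescence genes 1 rose and 1 fell, 2 and 2 adjusted within the list (0.897). SAG29 (AT5G13170, 1.99 ± 0.46) was lost without Ctrl library 2 (0.293) or 3 (0.126) or high-boron library 2 (0.0677) or 3 (0.173) and with voom (0.0643). AT4G11910 (-1.13 ± 0.25) was lost without Ctrl library 2 (0.358) or high-boron library 2 (0.218). Of 14 pectin genes 1 fell, RGXT3 (-1.21 ± 0.26; list 0.535), and of 31 wall loosening genes 1 rose, XTH15 (1.18 ± 0.21; 0.0579). Of 6 heat shock genes 1 fell, HSP90.1 (AT5G52640, -1.0 ± 0.20; 0.247). RGXT3 was lost without Ctrl library 2 (0.208) or high-boron library 2 (0.198), XTH15 without Ctrl library 2 (0.143) or high-boron library 3 (0.0665), and HSP90.1 without Ctrl library 3 (0.0762) or high-boron library 2 (0.164). Of 8 cellulose synthases (0.168), 17 cell cycle (0.64), 10 DNA damage (median 0.05, mean -0.03, upward; 0.943), 9 phosphate (median -0.00052, mean 0.07, upward; 0.622), 8 iron deficiency (0.247), 3 ferritin (median 0.14, mean -0.02, downward; 0.943) and 11 sulfur deficiency genes (0.173), the 3 tools called 0, with 0, 0, 2, 1, 0, 1 and 2 at unadjusted p < 0.05. Adjusted within the list, 1 ferritin gene fell.

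Of the genes tested in footprints, 350 were called at high boron (1.98%), 82 higher and 268 lower (76.6% lower), and 233 changed at least 2-fold, 178 of them lower. BAM5 (3.18 ± 0.32), UGT74E2 (2.58 ± 0.33), CYP81D11 (2.32 ± 0.32) and AT4G19430 (2.05 ± 0.21) were among the 6 largest rises, as in mRNA. The other large rises, AT5G55410 (2.19 ± 0.42) and the phosphate transporter PHT1;5 (AT2G32830, 2.07 ± 0.42), were lost without Ctrl library 2 (0.119 and 0.25) or high-boron library 2 (0.113 and 0.0922), AT5G55410 also without Ctrl library 3 (0.0677) and PHT1;5 without high-boron library 3 (0.0646). The largest falls were those of PCR1 (-3.20 ± 0.23), AT5G01710 (-3.12 ± 0.27), AT3G49340 (-2.50 ± 0.54), ARD3 (-2.41 ± 0.39), PUB54 (AT1G01680, -2.37 ± 0.28) and the glucanase BG3 (AT3G57240, -2.37 ± 0.22). ARD3 was lost without Ctrl library 2 (0.112), and AT3G49340 without Ctrl library 2 (0.154) or 3 (0.0588) or high-boron library 2 (0.15) or 3 (0.0882) and with voom (0.0617). The count was 140 without Ctrl library 2 (18 higher, 122 lower) and 131 without high-boron library 2 (37 higher, 94 lower). It was 668 with no filter on low counts and 209 with the strict filter.

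Translation efficiency fell for 121 genes and rose for 6 at high boron, of 17306 tested (95.3% of the 127 calls lower). AT5G01710 (-2.89 ± 0.26, adjusted p = 2.24e-05), AT5G58950 (-2.09 ± 0.19, adjusted p = 2.29e-05) and BOR1 fell and were called in every alternative run. AT2G41980 (-2.63 ± 0.46, adjusted p = 0.0105) was lost without footprint Ctrl library 2 (0.148) or RNA Ctrl library 3 (0.0519), and AT3G62270 fell as well. Of the 121 genes, 81 were called higher in mRNA and 1 lower, 40 were called lower in footprints, and 15 were called both higher in mRNA and lower in footprints. Their median log2 change was 0.42 in mRNA and -0.79 in footprints. Of the 6 rises, 3 were called lower in mRNA, 3 higher in footprints and 1 lower in footprints. BT2 (AT3G48360, 2.2 ± 0.38, adjusted p = 0.0101) was lost without RNA libraries 3 of Ctrl (0.0549) or 2 of high boron (0.0801). The count at high boron was 211 without footprint Ctrl library 3 (35 higher, 176 lower), 36 without RNA Ctrl library 3, 77 without RNA low-boron library 2 or 3, 52 without RNA high-boron library 2 and 49 without library 3. It was 58 in the 2-group fit, 168 with DESeq2 and 104 with voom.

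Flavonoid genes made up 2 of the 6 rises in translation efficiency at high boron. Of 13 tested 2 rose, 5 adjusted within the list (camera adjusted p = 2.38e-05; adjusted p = 0.0684 with correlation estimated; fry adjusted p = 0.0176): DFR (1.58 ± 0.32, adjusted p = 0.0278) and TT4 (1.28 ± 0.26, adjusted p = 0.0278). Both were lost without footprint Ctrl library 2 (0.117 and 0.147), RNA Ctrl library 2 (0.0617 and 0.0695) or 3 (0.177 and 0.161), or RNA high-boron library 2 (0.157 and 0.198) or 3 (0.107 and 0.0603), and in the 2-group fit (0.0525 for each). DFR was also lost without footprint high-boron library 2 (0.0993) or RNA low-boron library 2 (0.0547) or 3 (0.0536), and TT4 without footprint high-boron library 3 (0.0883). Of the other rises, AT3G28510 (1.87 ± 0.39, adjusted p = 0.0298) and AT3G26440 (1.42 ± 0.30, adjusted p = 0.0358) were lost without footprint Ctrl library 2 (0.0875 and 0.148) or high-boron library 3 (0.0858 and 0.0802). Left-out RNA libraries ended both as well: Ctrl 3 (0.17 and 0.177), low boron 2 (0.0547 and 0.0672) and 3 (0.0536 and 0.0677), and high boron 2 (0.125 and 0.203) and 3 (0.265 and 0.149). AT3G26440 was also lost without RNA Ctrl library 2 (0.0833) or footprint high-boron library 2 (0.0786) and with the span trend removed (0.0571). voom (0.114 and 0.0973) and the 2-group fit (0.092 and 0.113) called neither. Of 24 jasmonate genes the 3 tools called 0 in efficiency, with 5 at unadjusted p < 0.05, and 1 rose adjusted within the list, with the list called upward (2.38e-05; adjusted p = 0.65 with correlation estimated). Photosynthesis (downward) and sulfur deficiency (upward) were called at 0.0497 each (adjusted p = 0.898 and 0.708 with an estimated correlation), and both calls were lost with DESeq2 size factors. In the salicylic acid list 2 genes rose adjusted within the list (0.0685), and DESeq2 called 1. The other lists except boron transport had no member called in efficiency at high boron with edgeR or voom (1 oxidative stress gene with DESeq2) and adjusted p between 0.114 and 0.985. Among these, median, mean and test direction differed in sign for glucosinolate, ferritin, clock and root marker genes.

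**Figure D3:**
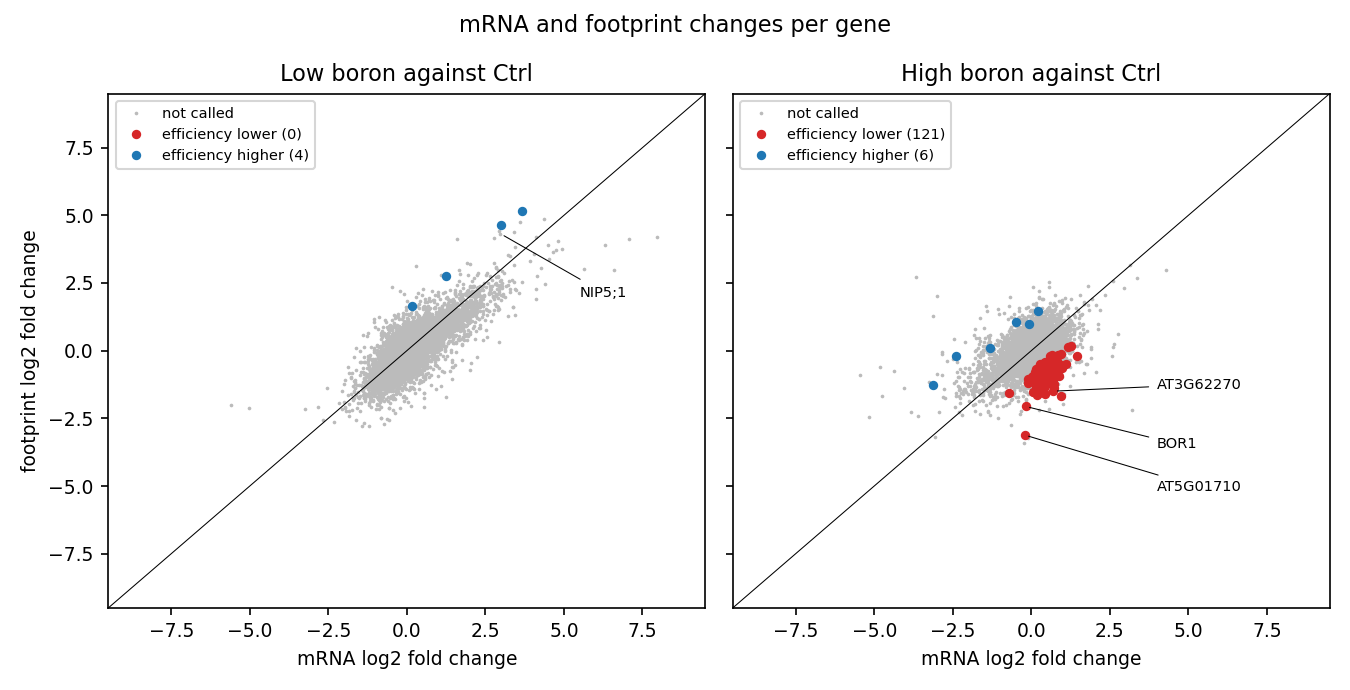
log2 fold change of footprints (vertical axis) against that of mRNA (horizontal axis) for 17306 genes at low boron and at high boron, each point 1 gene, with the line of equal change. Genes called lower in translation efficiency are red (0 at low boron, 121 at high boron) and those called higher blue (4 and 6), the rest grey.

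At low boron, translation efficiency rose for 4 genes and fell for 0 with edgeR, whereas 328 genes were higher and 721 lower at unadjusted p < 0.05. DESeq2 called 17 genes (13 higher, 4 lower) and voom 2 (2 higher, 0 lower). The 4 were CPUORF47 (1.63 ± 0.26, adjusted p = 0.0278), AT5G01710 (1.52 ± 0.19, adjusted p = 0.0045), AT2G34930 (1.51 ± 0.19, adjusted p = 0.0045) and AT3G53400 (1.5 ± 0.23, adjusted p = 0.0278). AT5G01710 was lost without footprint Ctrl library 2 (0.0557) and AT2G34930 without RNA Ctrl library 3 (0.0523), and both without RNA low-boron library 2 (0.114 each). CPUORF47 and AT3G53400 were both lost without footprint libraries 2 of Ctrl (0.436 and 0.379) and 2 and 3 of low boron (0.0931 and 0.0803, each for both genes). They were also lost without RNA libraries 3 of Ctrl (0.116 and 0.0912), 2 and 3 of low boron (0.225 and 0.236, each for both) and 2 and 3 of high boron (0.0728 and 0.0808, each for both), and AT3G53400 without RNA Ctrl library 2 (0.166). Both were lost with voom (0.235 and 0.0725), in the 2-group fit (0.0925 and 0.0736), with the block by number (0.0553 and 0.0544) and by plant pool (0.0594 each). The count was 0 without RNA low-boron library 2, 1 without footprint Ctrl library 2, 9 without footprint Ctrl library 3 (6 higher, 3 lower), and 2 without footprint low-boron library 3 or any 1 of RNA Ctrl library 3, low-boron library 3 or high-boron libraries 2 and 3.

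In translation efficiency at low boron, 9 lists besides boron transport and AUG-stop genes were called with camera at the preset correlation, all 11 without a member called by edgeR, and fry called 0 lists. Salicylic acid and defence (median -0.51, camera adjusted p = 7.75e-05), oxidative stress (-0.22, 0.00151), heat shock (-0.90, 0.00285), senescence (-0.33, 0.00507), the unfolded protein response (-0.24, 0.0185), glucosinolate (-0.28, 0.0194), jasmonate (-0.24, 0.0207) and cell cycle (-0.25, 0.039) were called downward. With an estimated correlation none was called, at adjusted p = 0.422, 0.495, 0.422, 0.422, 0.634, 0.784, 0.784 and 0.827. Chloroplast-encoded genes were called upward (median 0.51, 0.000467; adjusted p = 0.827 with correlation estimated), but they took at most 0.02312% of the RNA counts, from libraries of unknown preparation, so whether their efficiency compares with that of nuclear genes is not known. Adjusted within the list, 1 defence gene, 4 oxidative stress genes, 3 heat shock genes and 1 glucosinolate gene fell. DESeq2 called 1 heat shock gene and voom 0 members of these 9 lists, and at unadjusted p < 0.05 there were 7, 5, 3, 1, 1, 1, 4 and 1 in the order given and 1 chloroplast-encoded gene. The other lists except boron transport and AUG-stop genes had adjusted p between 0.126 and 0.957 and 0 members called with the 3 tools. Among them, median, mean and test direction differed in sign for cellulose synthases, abscisic acid and cold, iron deficiency, ferritin, clock and root marker genes.

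Between high and low boron, mRNA of 7799 genes was called (42.4%), 3553 higher and 4246 lower at high boron. Of these 2034 changed at least 2-fold (631 higher, 1403 lower). The largest rises were those of AT3G55710 (3.66 ± 0.33), SAUR68 (3.60 ± 0.59) and CYP81D11 (3.38 ± 0.14). AT1G33950 had 0 counts at high boron against 91 at low boron (ratio 0, 95% counting interval 0 to 0.0419). AT2G38240 had 1 count against 120 (ratio 0.00843, 95% counting interval 0.000212 to 0.0479), and AIG1 stood at -6.33 ± 0.17. In footprints 3660 genes were called (20.7%), 1653 higher and 2007 lower, and 1818 changed at least 2-fold (633 higher, 1185 lower). Footprints of CYP81D11 (3.04 ± 0.32), AT5G18030 (2.89 ± 0.52) and the protochlorophyllide reductase PORA (AT5G54190, 2.84 ± 0.28) were higher at high boron. Those of GAT1_2.1 (-7.16 ± 0.37) and AT3G53400 (-6.78 ± 0.27) were lower, and AT3G28600 had 1 count against 156 (ratio 0.0105, 95% counting interval 0.000265 to 0.0595). The footprint count was 2284 without low-boron library 2 and 1869 without low-boron library 3.

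Translation efficiency differed between high and low boron for 281 genes, 56 higher and 225 lower at high boron, 219 of them at least 2-fold. At unadjusted p < 0.05, 853 were higher and 859 lower. AT5G01710 (-4.41 ± 0.24, adjusted p = 2.19e-08) and AT3G53400 (-3.31 ± 0.27, adjusted p = 3.83e-06) were lower. AT1G61490 had 1 footprint against 53 (ratio 0.031, 95% counting interval 0.00077 to 0.18), a log2 change of -4.40 (-6.70 without footprint high-boron library 2), and was not called with DESeq2 (0.0535). OXS3 (AT5G56550, 2.38 ± 0.44, adjusted p = 0.00769) and AT2G04495 (2.31 ± 0.42, adjusted p = 0.00697) were higher, both lost without RNA high-boron library 2 (0.0706 and 0.092). The flavonoid glycosyltransferase UF3GT (AT5G54060, 2.41 ± 0.50, adjusted p = 0.0161) was lost without RNA low-boron library 2 (0.0502) or 3 (0.146) or high-boron library 2 (0.0958) or 3 (0.0745). The count was 149 without footprint low-boron library 2, 108 and 119 without RNA low-boron libraries 2 and 3, and 134 and 184 without RNA high-boron libraries 2 and 3.

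Changes in mRNA and footprints correlated more strongly at low than at high boron. Across 17306 genes, which are not independent replicates, the log2 changes correlated at r = 0.79 (Spearman 0.725) at low boron, 0.409 (0.289) at high boron and 0.822 (0.738) between high and low boron. Of the genes called in both assays, 2266 of 2268 at low boron, 218 of 233 at high boron and 3023 of 3089 between the supplies changed in the same direction. Of genes called in mRNA, 94.3%, 77% and 91% had a footprint change of the same sign (5660 of 6001, 1262 of 1638 and 6880 of 7560). At high boron the correlation was 0.27 without library 2 of Ctrl and 0.269 without library 2 of high boron in both assays.

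Genes called in both comparisons with Ctrl moved more often in opposite directions. In mRNA 508 genes rose at low boron and fell at high boron and 150 did the reverse, whereas 186 rose in both and 109 fell in both. Lists of these sizes drawn independently would share 163, 114, 161 and 116. In footprints the counts were 139, 4, 20 and 21, against 21.6, 5.68, 6.6 and 18.6. Across genes the 2 mRNA changes correlated at r = -0.207 and the footprint changes at 0.0124, where 20 simulations with no effect gave 0.495 and 0.53 because both comparisons share the Ctrl libraries. In these simulations 0.1 genes on average were called higher in both and 0.25 lower in both for mRNA, and 0.1 and 0.15 for footprints. What the shared controls add among genes that do change was not measured.

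Of 13 circadian clock genes 9 were called in the same direction in mRNA at both supplies (0 in 20 simulations with no effect and shared Ctrl libraries), 13 had the same sign (8.5 simulated, SD 1.7), and 4 were called different between high and low boron. In mRNA 4 of 13 rose and 7 fell at low boron, 4 and 8 adjusted within the list (median -0.27, mean 0.05, downward; camera adjusted p = 0.0719). At high boron 4 rose and 6 fell, 5 and 6 adjusted within the list (median -0.09, mean 0.10, downward; 0.372). CCA1 (AT2G46830), which peaks at dawn, rose by 1.48 ± 0.16 and 1.85 ± 0.16, while ELF4 (AT2G40080), an evening gene, stood at -1.33 ± 0.12 and -1.21 ± 0.12 and GRP7 (AT2G21660) at -0.96 ± 0.08 and -0.90 ± 0.08. In footprints 1 rose and 2 fell at low boron, 2 and 4 adjusted within the list (median -0.19, mean 0.02, downward; 0.231). At high boron 1 rose and 2 fell (median -0.12, mean 0.10, downward; 0.622). ELF4 (-1.35 ± 0.20 at low boron) was called at low boron with each library left out. FKF1 (AT1G68050, -0.68 ± 0.18) was lost at low boron without Ctrl library 3 (0.0875) or low-boron library 3 (0.228). CCA1 (1.16 ± 0.32) was lost without Ctrl library 2 (0.175) or low-boron library 2 (0.269). At high boron TOC1 (AT5G61380, -1.22 ± 0.22) was lost without Ctrl library 3 (0.0569) or high-boron library 2 (0.0878). CCA1 (1.49 ± 0.32) was lost without Ctrl library 2 (0.257) or 3 (0.0687) or high-boron library 2 (0.137) or 3 (0.0611). ELF4 at high boron (-0.79 ± 0.19) was lost without Ctrl library 2 (0.442), low-boron library 2 (0.0625) or 3 (0.0618), or high-boron library 2 (0.141) or 3 (0.167), under the strict filter (0.0645), with voom (0.0581) and in the 2-group fit (0.0659).

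Markers of other tissues were mostly too low to test. Of 3 root marker genes tested in mRNA, the root glucosidase PYK10 (AT3G09260) rose at low boron (0.63 ± 0.14, 0.35 without Ctrl library 2) and fell at high boron (-0.94 ± 0.15, -0.61 without Ctrl library 3), and DESeq2 did not call the rise (0.0705). The nitrate transporter NRT2:1 (AT1G08090) fell at low boron (-0.62 ± 0.17), lost without low-boron library 3 (0.13). Adjusted within the list, 1 root gene rose and 1 fell at low boron and 1 rose and 2 fell at high boron, and the list was not called (0.909 and 0.272). In footprints the 3 tools called 0 of 6 root genes (0.406 and 0.254), with 1 at unadjusted p < 0.05 at each supply, and 1 fell at high boron adjusted within the list. Of 3 floral genes in mRNA the 3 tools called 0 at low boron, with 0 at unadjusted p < 0.05 (0.56), and SEP3 (AT1G24260, 0.95 ± 0.23) rose and PI (AT5G20240, -1.30 ± 0.37) fell at high boron (0.824). SEP3 was lost without Ctrl library 3 (0.121) or high-boron library 2 (0.0887) or 3 (0.0927) and with DESeq2 (0.0804). PI was lost without Ctrl library 2 (0.245), low-boron library 2 (0.0812) or 3 (0.0809), or high-boron library 2 (0.152) or 3 (0.194), with DESeq2 (0.213), with voom (0.0641) and in the 2-group fit (0.0728). In footprints 1 of 6 floral genes fell at low boron (SEP1, AT5G15800, -2.48 ± 0.70; 0.133), lost without Ctrl library 2 (0.0527) or 3 (0.151) or low-boron library 2 (0.187) or 3 (0.111). At high boron the 3 tools called 0 floral genes, with 4 at unadjusted p < 0.05, and 2 rose and 1 fell adjusted within the list (0.0494; adjusted p = 0.433 with correlation estimated). Of 2 seed storage genes tested in footprints edgeR and DESeq2 called 0 and voom 1 at low boron and 0 at high boron, with 1 and 0 at unadjusted p < 0.05 and 0 adjusted within the list (0.222 and 0.882).

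The ribosomal protein list, meant to be cytosolic, was not called. The named members that fell are known as plastid proteins, so it does not test cytosolic ones alone. Of 46 tested in mRNA at low boron 1 rose (SAG24) and 7 fell (0.133), with RPL9 (AT3G44890) at -0.80 ± 0.08, RPL12-C (AT3G27850) at -0.71 ± 0.07 and RPS9 (AT1G74970) at -0.68 ± 0.08. In footprints 1 rose and 6 fell, 1 and 7 adjusted within the list (0.133). RPL9 (-0.99 ± 0.18) was lost without low-boron library 3 (0.0513). RPL15 (AT3G25920, -0.80 ± 0.19) and RPS9 (-0.81 ± 0.19) were lost without Ctrl library 2 (0.064 and 0.0563) or low-boron library 3 (0.163 and 0.152). At high boron the 3 tools called 0 of 46 in mRNA and in footprints (0.454 and 0.64), with 5 and 4 at unadjusted p < 0.05.

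Chloroplast-encoded genes took 0.01555% to 0.02312% of the RNA counts. The footprint shares of libraries 2 and 3 were 4.905% and 4.039% in Ctrl, 7.409% and 3.975% at low boron, and 8.139% and 2.789% at high boron. Of 34 chloroplast-encoded genes tested in mRNA 5 fell at low boron and 0 adjusted within the list (0.163). ATCG00480 (-0.53 ± 0.15) was lost without Ctrl library 3 (0.108) or low-boron library 2 (0.0622) or 3 (0.0909), ATCG00680 (-0.82 ± 0.26) without Ctrl library 2 (0.122) or low-boron library 2 (0.219). ATCG00170 (-1.24 ± 0.39) was lost without low-boron library 2 (0.257). DESeq2 called none of these 3 (0.0813, 0.132 and 0.0688). At high boron 1 rose (ATCG00490, the Rubisco large subunit, 0.71 ± 0.18; 0.454), lost without Ctrl library 3 (0.113) or high-boron library 2 (0.177). In footprints the 3 tools called 0 of 72 at low (0.809) and high boron (0.00488), with 2 and 10 at unadjusted p < 0.05. They called 0 of 17 mitochondria-encoded genes (0.158 and 0.0382), with 1 at each supply at unadjusted p < 0.05. Both lists were called upward at high boron (adjusted p = 0.921 with correlation estimated). Their shares in high-boron library 2 lay above both Ctrl libraries and in library 3 below, so the direction rests on library 2. Mitochondria had 0.03388% and 0.006675%, against 0.01179% and 0.01579% in Ctrl.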

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

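The removal of a trend with genomic span and the test of gene families were chosen after seeing the data, the other alternatives beforehand. The 2 libraries per group limit every test: with 1 left out, the remaining library is assumed to vary like the others, and regroupings of 2 against 2 libraries are too few to test chance. No equal-number correlation of deviations between groups exceeded 0.156 (RNA 0.0258, 0.0599 and -0.0198, footprints 0.156, -0.0109 and 0.0931), and between assays they were 0.0258, -0.0269 and -0.0037. With the number as a block, calls at low boron, high boron and between the supplies were 6156, 1646 and 7828 for mRNA, 3208, 497 and 4182 for footprints, and 2, 161 and 329 for translation efficiency (2, 125 and 316 with the plant pool as a block). Across named genes, DESeq2 size factors in edgeR, TMM over all libraries and removal of organelle-encoded genes changed 0 directions and ended 0 of 254, 20 and 250 calls. Of the called lists, DESeq2 size factors turned 0 and ended 2, photosynthesis and sulfur deficiency in translation efficiency at high boron. DESeq2 ended 23 of 251 calls and added 1, voom ended 11 of 254, the fit of only the groups compared 18 of 252, the strict filter 2 of 152, the block by number 2 of 254, the block by plant pool 2 of 20 and the removal of the span trend 1 of 20, and no filter added 1. Of 54 list calls, camera with an estimated correlation ended 54, fry ended 39 and added 3, and camera with the replicate block ended 1 and added 2. Of named calls that held with every library left out there were 53 of 68 for mRNA at low boron, 39 of 58 at high boron, 32 of 58 and 14 of 38 for footprints, 0 of 4 and 3 of 10 for translation efficiency, and 6 of 6, 6 of 6 and 3 of 6 between the supplies. With 1 library left out, called genes ranged from 3731 to 6102 for mRNA at low boron, 784 to 1894 at high boron and 5344 to 8531 between the supplies. For footprints they ranged from 922 to 2924, 131 to 310 and 1869 to 3939, and for translation efficiency from 0 to 9, 36 to 211 and 108 to 371. The correlation of mRNA and footprint changes, with an equal-numbered library left out of both assays, ranged from 0.651 to 0.7 at low boron, 0.269 to 0.33 at high boron and 0.7 to 0.769 between the supplies, and over genes with a log2 CPM of 3 or more it was 0.869, 0.506 and 0.868. DESeq2 called 4030 mRNA changes at low boron (2416 higher, 1614 lower), 963 at high boron (445 and 518) and 17 translation efficiency changes at low boron. A 2-fold minimum, which can only remove calls, left 1250, 349 and 2034 mRNA changes and 1114, 233 and 1818 footprint changes. With it, the numbers called at both supplies were 18 higher in both, 11 lower in both, 141 higher at low and lower at high boron and 7 the reverse for mRNA, and 10, 3, 75 and 1 for footprints. At high boron, footprint calls were 668 with no filter (191 higher, 477 lower) and 209 with the strict filter (47 and 162). Translation efficiency calls at low boron were 1 with the strict filter, and 2 with voom, with only the groups compared, with the block by number and with the block by plant pool. At high boron they were 58 with only the groups compared (1 higher, 57 lower). Lists called with camera were 9 and 7 for mRNA at low and high boron, 11 and 11 for footprints, and 11 and 5 for translation efficiency. With an estimated correlation these were 0 in all 6 cases. With fry they were 11 and 1 for mRNA, 5 and 0 for footprints, and 0 and 1 for translation efficiency.

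The signs that turned all belonged to changes that were not called. With 1 library left out, BOR1 mRNA at low boron ranged from -0.057 to 0.148, BOR5 mRNA at low boron from -0.73 to 0.13 and AT3G06450 mRNA at high boron from -0.0584 to 0.0198. BOR5 footprints at low boron ranged from -0.56 to 0.67, and were -0.0423 with DESeq2 and -0.0090 with the block by number. At high boron, footprints of AT3G06450 ranged from -0.17 to 0.21, of BOR5 from -0.58 to 1.41 and of ABS2 from -0.0615 to 0.42. Translation efficiency at low boron ranged from -0.0825 to 0.30 for AT3G06450, -0.18 to 1.05 for BOR5 and -0.26 to 0.11 for NIP6;1, which was 0.0086 with the span trend removed. At high boron it ranged from -0.15 to 0.24, -0.96 to 1.04 and -0.088 to 0.0606 for these 3 genes. Lists that turned were sulfur deficiency (adjusted p = 0.95) and root markers (0.891) in mRNA at low boron and anthocyanin in footprints at low boron (0.915) with fry, and root markers in mRNA (0.955) and chloroplast-encoded genes in footprints (0.945) at low boron with the replicate block. In translation efficiency at low boron, fry turned cellulose synthases (0.979), abscisic acid and cold (0.82), iron deficiency (0.936) and ferritin (0.958). For all these changes, the cause was not tested.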

Other observations

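The gene families, the removal of the span trend and the test of the harvest time were chosen after the result was seen, as was the use of alternatives fixed beforehand to test the one-sided translation efficiency. Families of genes with a shared symbol prefix, 166 for mRNA, 168 for footprints and 164 for translation efficiency, were tested with camera, and with an estimated correlation no family was called (adjusted p = 0.435 to 0.991 for those given). Of 37 cysteine-rich receptor kinases (CRK) 24 rose and 1 fell in mRNA at low boron, with CRK37 at 4.04 ± 0.20 (camera adjusted p = 1.28e-14). Of 51 WRKY transcription factors 25 rose and 1 fell (1.8e-07). At high boron 12 CRK genes fell and 1 rose (7.99e-11), and 13 WRKY genes fell and 2 rose (4.14e-06).

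Of 14 PTAC genes, whose proteins belong to the plastid transcription complex, 13 fell in mRNA at low boron (8.43e-07), and 8 fell in footprints (2.01e-05). Of 10 casein kinase 1-like (CKL) genes at high boron, 5 rose in mRNA (0.000506), 2 fell in footprints (0.00946) and 5 fell in translation efficiency, with ckl7 at -1.70 ± 0.20 (3.58e-11).

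Of 13 clock genes 9 were called in the same direction in mRNA at both supplies. One Ctrl RNA library out of place is argued against by a test written beforehand: without either Ctrl RNA library 8 genes were called in the same direction in both. A harvest of the Ctrl plants at another time of day might account for the pattern. Of 9 of the 13 genes, picked after the result, 4 dawn genes were higher and 5 evening genes lower. A shift common to both supplies does not cover the 4 clock genes called different between the supplies, but 42.4% of all mRNAs were. Harvest time cannot be told apart from an effect of both supplies on the clock, as the labels give no time.

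Of the 127 translation efficiency calls at high boron, 95.3% were decreases, against 879 lower and 550 higher at unadjusted p < 0.05. Scaling of the libraries cannot be told apart: the share was 95.3% at the lowest under DESeq2 size factors and TMM over all libraries, but these only moved the median over all genes from 0.0295 to 0.0283 and 0.019, too little to test it. A single library is argued against: with each of the 8 libraries left out the share was at least 75.6%, the lowest without RNA Ctrl library 2 (22 higher, 68 lower) and the rest between 83.4% and 98.9%. A trend with gene length stays open too: with the trend with genomic span removed the share was 95.3%, but this moved the changes by an SD of only 0.0194, and of 3 equal sets of genes by span the longest had a median of 0.043 but held 77 of the 121 decreases, the shortest 5. Whether boron lowers the translation of these mRNAs, for instance through AUG-stops, stays open, as no leader sequences were used here.

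The correlation of mRNA and footprint changes was 0.409 at high and 0.79 at low boron. Noise could lower it: estimation error was 52.6% of the variance of footprint changes at high and 22.8% at low boron. With this error removed, a test written beforehand, r was 0.701 (SD over resampled genes 0.02) and 0.956 (SD 0.0043), a difference of 0.255. With 1 library left out it was 0.533 to 0.765 at high and 0.883 to 1.02 at low boron. Groups were assumed to vary alike, but footprint replicates varied most at high boron (chi-square per df 25.3, low 18.11, Ctrl 12.27). Noise and a separate response of translation there stay open.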
